A study of Drosophila melanogaster with 15 samples.

How the data were processed

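The mRNA libraries were made from total RNA of SL2 cells with a standard Illumina TruSeq protocol, per the labels' protocols. There were 3 of them, for control RNAi, CLAMP RNAi and MSL2 RNAi, with 1 library per group. The labels do not say which sequence the control RNAi was directed against. The 12 immunoprecipitation and input libraries of the series were not analysed here.

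Each deposited file lists 22353 transcripts, without a header, with 1 RPKM value, 1 read count, a transcript length and the library total on each line. Bowtie, a short-read aligner, and the dm3 genome build are named in the submitters' processing notes. The Bowtie version, the counting tool, the annotation release and the use of strand are not given in the sources used here. The deposited RPKM values equal the deposited read count divided by the transcript length and the library total and put on the usual RPKM scale, as recomputed from the files. No other scaling between libraries was applied by the authors as far as the values show. The deposited counts are whole reads per transcript. Their sum is 139678971 in the control file against a library total of 68036170, because reads in exons shared by several isoforms enter the count of each isoform. Reads of overlapping genes, antisense partners and near-identical copies could not be told apart.

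A single transcript therefore stood for each gene, the one with the most reads on average over the libraries, a choice made after the files were seen. This gave 15139 genes, of which 3632 had several transcripts. The chosen transcripts held 64647297 reads in control, 65304523 after CLAMP RNAi and 64612655 after MSL2 RNAi, or 95.0%, 95.6% and 95.2% of the totals, if counts and totals are in the same unit. The 10 most counted genes took 8.80%, 9.12% and 9.70% of the reads. Gene symbols, chromosome arms and gene order were taken from an annotation table of the Release 6 plus ISO1 MT assembly. That assembly differs from the build of the files, so no coordinates are given. Identifiers matched by locus tag for 13783 genes and by a unique synonym for 749, and 607 stayed unmatched. Gene models matched through a synonym keep their own identifier as their name. A few members of the gene lists found no match and were not analysed here.

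Genes with a mean RPKM of at least 1 over the 3 libraries were tested, 7485 in all. They comprise 1289 on the X, 6058 on arms 2L, 2R, 3L and 3R, 57 on chromosome 4 and 81 without an assigned arm. For each pair of libraries the log2 ratio of RPKM plus a pseudocount of 0.1 was computed, a scale that understates the change of low genes. The main result is the median log2 ratio of X-linked genes minus that of the 4 major autosomal arms, which does not depend on library scaling. Its 95% interval is the binomial order-statistic interval of the X median, with the autosomal median taken as fixed. It gives the precision of that median with genes treated as independent, and not the spread of single genes. Ratios of neighbouring X-linked genes were correlated, so the interval may be too narrow. Shares of genes have exact Clopper-Pearson intervals. Read ratios of single genes, scaled by library totals, have exact Clopper-Pearson counting intervals. Although counts were present, no count model could be fitted across samples with 1 library per group, so genes were described by fixed rules of size, 2-fold for genes and 1.5-fold where stated.

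Lists of genes, chromosomes and transcript classes were placed among 10000 random lists of the same size drawn from the tested genes and matched on decile of mean RPKM. The percentile describes these libraries and is not a test across cultures. The 26 gene lists were fixed before the data were examined, and each had at least 3 tested members. Random lists matched also on X-linkage, and lists without X-linked genes for chromosome 4, were added after seeing the data. The text names the RNAi targets and every MSL complex and roX gene. Among genes with a mean RPKM of at least 5 it names, per comparison with control, the 6 X-linked genes with the lowest and the 4 with the highest ratio, and the 6 lowest and 6 highest autosomal genes. In each list described it names 1 to 4 members of largest absolute log2 ratio, except 1 gene that is not reported here. The rule was fixed before the data were examined. Genes named outside it (Prx6b, nej beside CG15321, and those of chromosome 4) were chosen after their values were seen.

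Shared genes between the comparisons with control were counted beside the number for independent lists and beside 100 simulations of counting noise against the same control. Each simulated gene had the same rate in every library. Alternatives changed 1 choice at a time: pseudocounts of 0.01 and 1, no level filter, a mean RPKM of at least 5, transcripts of at least 1 kb, a mean trimmed by 10% at each end, autosomes with chromosome 4, scaling to an autosomal median of 0, upper-quartile scaling and a 2-fold rule. The longest transcript per gene and the mean RPKM over isoforms were added after seeing the data. The statistics were tested on simulated counts for 7347 genes. A shift of −0.4 put on the X in the MSL2 RNAi comparison came back as −0.40, and 0 in the CLAMP RNAi comparison as 0.00. All genes changed by a log2 of 1.5 or 3 passed the 2-fold rule, as did 0.154% of unchanged autosomal genes, and 95.8% of the counting intervals held the true ratio. The simulation held counting noise only, so these shares do not cover differences between cultures. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.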

Results

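The series holds 15 samples of Drosophila cell lines. SL2 is a male line of embryonic origin and Kc is a female one. CLAMP is a zinc finger protein, and MSL2 is a subunit of the male-specific lethal (MSL) complex, which acts with the noncoding roX RNAs on the male X chromosome. In RNA interference (RNAi), double-stranded RNA lowers the transcript whose sequence it matches. Messenger RNA of SL2 cells was sequenced after 6 days of RNAi at 25 °C in 1 control library, 1 CLAMP RNAi library and 1 MSL2 RNAi library. The other 12 samples, chromatin immunoprecipitation of CLAMP and its input DNA, were not analysed here. The library totals by which the RPKM values were scaled were 68036170 for control, 68301197 for CLAMP RNAi and 67844405 for MSL2 RNAi, which are nearly equal. Whether these totals count reads or mates, and all mapped reads or only those on transcripts, is not given in the sources used here. With 1 library per group, no difference below has a replicate check and no p-value across samples was possible. "Lower" and "higher" describe these libraries. Read intervals cover counting error only and treat every read as independent. They may be too narrow even for that, since mates of a pair and PCR copies are not independent molecules.

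Each RNAi target was lower in its own library and close to the control level in the other knockdown library. Clamp (CG1832, arm 2L) had an RPKM of 66.2 in control, 19.8 after CLAMP RNAi and 66.9 after MSL2 RNAi. Its read ratio to control was 0.299 after CLAMP RNAi (exact 95% counting interval 0.288 to 0.311) and 1.01 after MSL2 RNAi (0.985 to 1.04). The msl-2 gene (CG3241, arm 2L) had an RPKM of 19.8 in control, 19.4 after CLAMP RNAi and 5.16 after MSL2 RNAi. Its read ratio was 0.260 after MSL2 RNAi (0.245 to 0.276) and 0.976 after CLAMP RNAi (0.938 to 1.01).

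The roX RNAs were far lower after MSL2 RNAi and moved less after CLAMP RNAi. The RPKM of roX1 was 303 in control, 270 after CLAMP RNAi and 102 after MSL2 RNAi, with log2 ratios to control of −0.17 and −1.57. For roX2, 684 reads in control compared with 463 after CLAMP RNAi and 140 after MSL2 RNAi. The log2 ratios of roX2 were −0.56 and −2.22. The genes of the other MSL proteins stayed within 1.5-fold of control in both libraries. Their log2 ratios after CLAMP RNAi were −0.11 for msl-1, −0.05 for msl-3, −0.18 for mle, the RNA helicase gene, and −0.14 for mof, the histone acetyltransferase gene. After MSL2 RNAi they were 0.00, 0.17, −0.06 and −0.18 in the same order. Of the 7 MSL complex and roX genes as a list, 0 were 2-fold lower after CLAMP RNAi and 3 after MSL2 RNAi, namely msl-2, roX1 and roX2. The list's median log2 ratio was −0.14 after CLAMP RNAi and −0.18 after MSL2 RNAi, and these medians stood at percentiles 19.5 and 12.9 of the random lists.

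**Figure D1:**
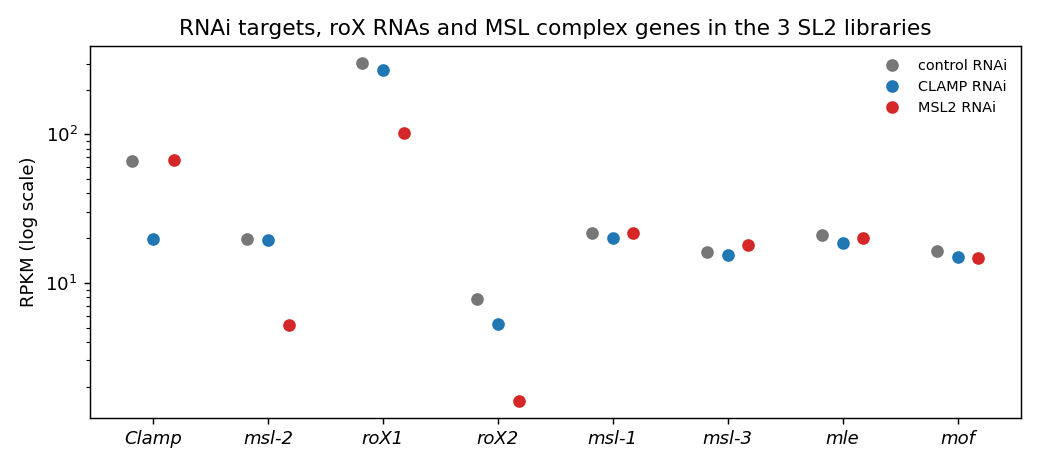
RPKM on a log axis of the RNAi targets, roX RNAs and MSL complex genes, with 1 point for each of the control, CLAMP RNAi and MSL2 RNAi libraries and no error bars because each group has 1 library. Clamp is at 19.8 in the CLAMP RNAi library against 66.2 in control, while msl-2, roX1 and roX2 are lowest in the MSL2 RNAi library.

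The study asked what CLAMP does for genes on the X chromosome. After CLAMP RNAi, X-linked genes as a group had about the same median ratio to control as autosomal genes. The median log2 ratio was −0.05 over 1289 X-linked genes and −0.05 over 6058 genes of the major autosomal arms. The difference was 0.00 (95% interval over genes −0.02 to 0.01), and 49.8% of X-linked genes lay below the autosomal median. The X median stood at percentile 83.6 of 10000 random gene lists matched on expression level. A ratio at least 1.5-fold lower was seen for 42 X-linked genes, or 3.26% (exact 95% interval 2.36 to 4.38), and for 237 autosomal genes, or 3.91% (3.44 to 4.43). The X-linked share depended on the level filter, at 5.19% without it and 1.90% at a mean RPKM of at least 5. The interval over genes leaves out any difference between separate cultures. Clamp RNA remained at a read ratio of 0.299 to control in the CLAMP RNAi library, and these libraries do not measure the protein. The near-equal medians therefore do not show that X-linked expression is independent of CLAMP.

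Individual genes did differ between the CLAMP RNAi and control libraries. Of 7347 genes on the X and the major arms, 87 were at least 2-fold lower and 43 at least 2-fold higher. The X held 14 of the lower and 6 of the higher ones. The lowest autosomal ratios belonged to Wsck, a receptor tyrosine kinase gene (log2 −3.30), Erasp (−3.12), Lac, which encodes the cell adhesion protein Lachesin (−3.09), and Itgbn, an integrin subunit gene (−2.71). Wsck had 5383 reads in control, 531 after CLAMP RNAi and 5873 after MSL2 RNAi, and Lac had 10323, 1208 and 11014. PCB, the pyruvate carboxylase gene, was lower in both knockdown libraries (−1.96 and −1.38), whereas the thiol reductase gene GILT3 stood at −1.80 and −0.25. On the X, the lowest were CG6891 (−2.11), CG15347 (−1.70), CR40469 (−1.52), CG11655 (−1.50), Nrg, which encodes the adhesion protein Neuroglian (−1.13), and the insulin-like peptide gene Ilp6 (−1.09). CR40469 is a noncoding transcript of 242 bases, and transcripts under 400 bases were lower as a class in both knockdown libraries (medians −0.15 and −0.16).

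Among genes higher after CLAMP RNAi, Ama, which encodes the immunoglobulin-family protein Amalgam, had 670 reads in control and 4432 after CLAMP RNAi (log2 2.70) but 261 after MSL2 RNAi (−1.32). CG4970 (2.20), CG34232 (1.70), the growth-blocking peptide gene Gbp1 (1.61), the chloride channel gene ClC-a (1.60) and the cytochrome P450 gene Cyp9c1 (1.53) followed on the autosomes. ClC-a too was on opposite sides of control in the knockdown libraries, at −1.96 after MSL2 RNAi. On the X, the highest were CG34331 (2.47, from 98 to 564 reads), the arginase gene arg (1.29), CG4829 (1.12) and the monocarboxylate transporter gene Mct1 (1.10). The last 3 of these stood at −0.62, −0.78 and −1.01 after MSL2 RNAi. The number of genes past the 2-fold rule depended on the level filter and the pseudocount. Without the filter it was 241 lower and 131 higher, at a mean RPKM of at least 5 it was 32 and 20, and with a pseudocount of 1 the lower genes numbered 43.

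Of 26 gene lists fixed before the data were examined, 6 had a median after CLAMP RNAi outside the central 95% of random lists. Over both comparisons with control this held for 8 of 52 medians, beside 2.6 for lists whose genes vary independently. Members of a list may vary together, so the excess over 2.6 does not show that a knockdown changed the lists. The 8 include the X-linked housekeeping list after MSL2 RNAi, whose level-matched percentile reflects the X-wide fall given below. With random lists matched also on X-linkage, a choice made after the data were seen, 10 medians lay outside the central 95%. After CLAMP RNAi the autosomal median log2 ratio rose with expression level, from −0.15 in the lowest decile to 0.04 in the highest. Counts of members above or below the autosomal median therefore partly reflect level, which the percentiles take into account. Proteasome genes, for example, were above it for 22 of 32 members at percentile 51.9. The hemocyte markers, genes of the blood cell type that SL2 resembles, lay above the autosomal median after CLAMP RNAi for 15 of 19 members (list median 0.14, percentile 99.9). The peroxidasin gene Pxn had a log2 ratio of 1.40, hemolectin Hml 1.00, SPARC 0.69 and papilin Ppn 0.54. The cytosolic ribosomal protein genes were above it for 63 of 85 members (median 0.10, percentile 99.96). This was a small shift with exceptions, since RpL39 stood at −0.81, RpL38 at −0.65 and RpS21 at 0.61. The antimicrobial peptide and immune recognition genes were above it for 15 of 21 members (median 0.05, percentile 98.0). At a mean RPKM of at least 5, however, the 12 remaining members had a median of 0.02 (percentile 86.7), within the central 95%. Their extremes were low in reads. Mtk, the metchnikowin gene, had 49 reads in control and 125 after CLAMP RNAi, and PGRP-LB, a peptidoglycan recognition gene, had 153 and 56.

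The other 3 such lists had lower medians after CLAMP RNAi. Lipid and sterol synthesis genes lay below the autosomal median for 8 of 10 members (median −0.22, percentile 0.190), with the acetyl-CoA carboxylase gene ACC at −0.60, the desaturase gene Desat1 at −0.57 and the lipase gene bmm at −0.32. Germline markers, a list of another cell type, were below it for 6 of 7 members expressed here (median −0.28, percentile 0.350), with AGO3 at −0.56, piwi at −0.52 and stwl at −0.35. Histone gene expression factors were below it for 8 of 10 members (median −0.19, percentile 1.81), with His3.3B at −0.46 and Lsm11 at −0.41. In the lipid list 1 member was 1.5-fold lower, and in the other lower lists 0. In MSL2 RNAi over CLAMP RNAi, which leaves the control out, lipid genes were at 0.04 (percentile 49.0) and histone factors at 0.09 (78.5). An unusual control library therefore stays open for both lists. Germline markers were at 0.26 (99.5) and hemocyte markers at −0.26 (0.06), so a difference remained there. Cytosolic ribosomal protein genes were at −0.02 (7.3) and immune genes at −0.05 (6.11, or 1.55 matched also on X-linkage).

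After MSL2 RNAi, X-linked genes as a group were lower than autosomal genes. The median log2 ratio to control was −0.33 on the X and 0.03 on the major autosomal arms. The difference of −0.36 (95% interval over genes −0.37 to −0.34) corresponds to a ratio of 0.781. Of the 1289 X-linked genes, 1179 or 91.5% lay below the autosomal median. The X median lay below all 10000 level-matched random lists, the lowest of which had a median of −0.05. The difference held a similar size across expression deciles, from −0.28 to −0.41, and across quintiles of transcript length, from −0.34 to −0.39. At least 1.5-fold lower were 192 X-linked genes, or 14.9% (exact 95% interval 13.0 to 17.0), and 193 autosomal genes, or 3.19% (2.76 to 3.66). A 2-fold rule left 22 X-linked genes, or 1.71%.

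The absolute level moved the same way. The X-linked median RPKM divided by the autosomal one was 0.943 in control (95% interval over X-linked genes 0.869 to 1.00), 0.933 after CLAMP RNAi (0.880 to 1.01) and 0.745 after MSL2 RNAi (0.693 to 0.797). Overlapping stretches of 57 neighbouring X-linked genes had median log2 ratios after MSL2 RNAi between −0.54 and −0.15, so no such stretch reached the autosomal median. The medians of the 4 major autosomal arms lay between 0.01 and 0.04. The small chromosome 4 was also lower, at a median log2 ratio of −0.34 over 57 genes after MSL2 RNAi and −0.34 after CLAMP RNAi. Relative to the major arms these were ratios of 0.777 and 0.822.

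**Figure D2:**
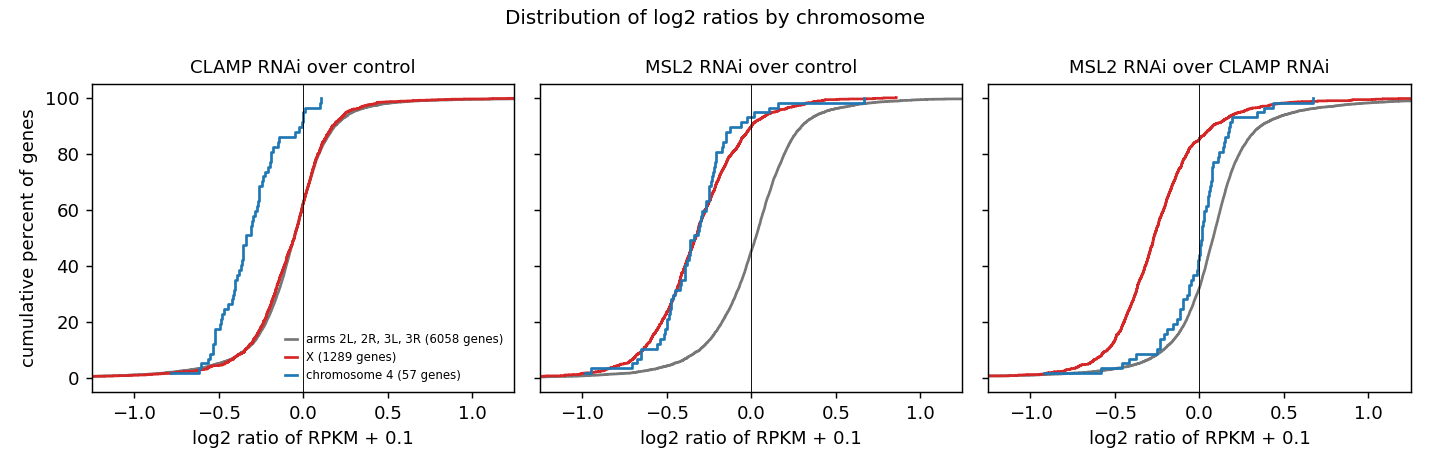
Cumulative percent of genes by log2 ratio of RPKM plus 0.1 in the 3 comparisons, for 1289 X-linked genes, 6058 genes of the major autosomal arms and 57 genes of chromosome 4. The X curve overlies the autosomal curve for CLAMP RNAi over control and lies to its left in both comparisons that hold the MSL2 RNAi library; chromosome 4 lies to the left in both comparisons with control.

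**Figure D3:**
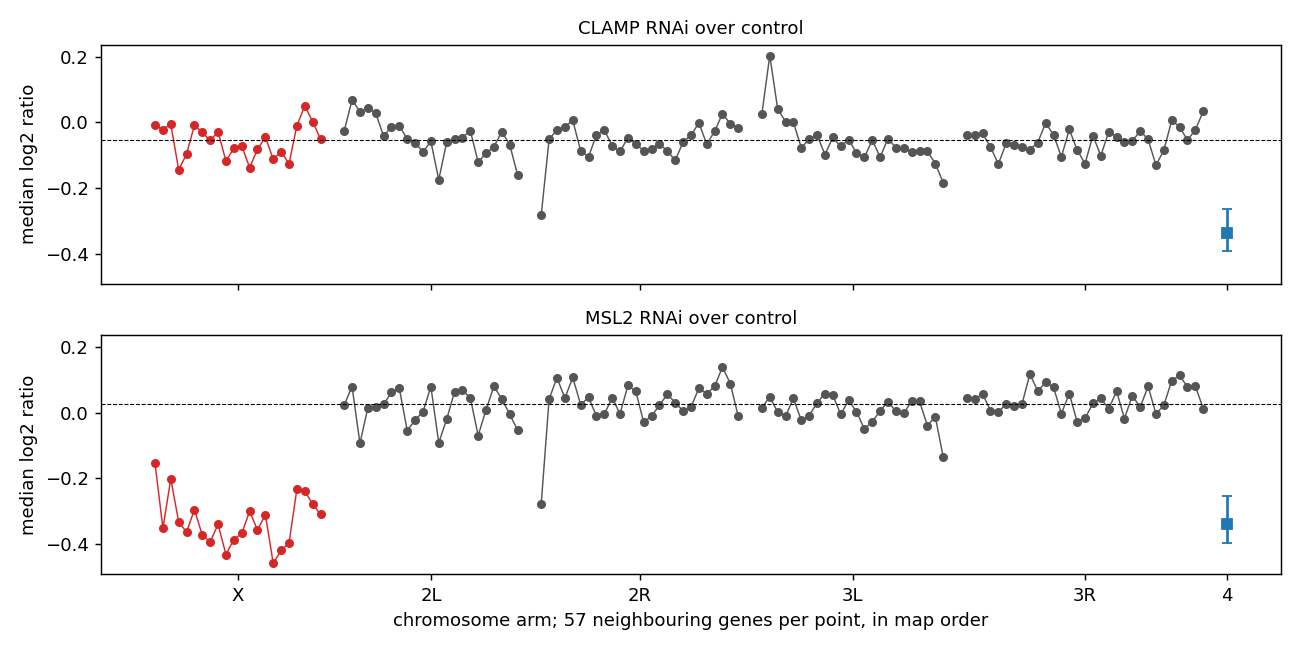
Median log2 ratio to control of consecutive stretches of 57 genes along each chromosome arm in map order (points), with the autosomal median as a dashed line and chromosome 4 as a square whose bars are the 95% interval of the median over its 57 genes. After MSL2 RNAi every stretch of the X lies below the dashed line, while the stretch of 2R nearest the centromere and chromosome 4 lie below it in both panels.

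Single genes after MSL2 RNAi numbered 72 at least 2-fold lower and 44 at least 2-fold higher among the same 7347. All 44 of the higher ones were autosomal. The lowest X-linked ratios among well-expressed genes were those of Vago, an antiviral response gene (log2 −2.50, 711 reads in control and 121 after MSL2 RNAi), CR40469 (−1.74), roX1 (−1.57), CG15321 (−1.56), Nrg (−1.41) and CG7267 (−1.23). CG15321 is an older gene model that the current annotation merges with nej, the CREB-binding protein gene, which stood at −0.82. On the autosomes the lowest were the acyltransferase gene Agpat2 (−2.35), ClC-a (−1.96), msl-2 itself (−1.92), RpL39 (−1.58), the small noncoding RNA CR33789 (−1.56) and the peroxiredoxin gene Prx6c (−1.43). RpL39 and CR33789 are transcripts of 289 and 46 bases. The median of transcripts under 400 bases was −0.15 after CLAMP RNAi and −0.16 after MSL2 RNAi. Prx6c has a close copy, Prx6b, at −1.23, and the counting could have divided their reads. Prx6c and RpL39 were lower after CLAMP RNAi too, at −1.24 and −0.81.

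The highest autosomal ratios after MSL2 RNAi were those of CG8620 (log2 1.66), Ptth, which encodes prothoracicotropic hormone (1.54), CG34437 (662 reads in control and 1875 after MSL2 RNAi), Marf1 (1.41), CG3788 (1.40) and CG30339 (1.15). No X-linked gene reached 2-fold. The highest on the X were CG5273 (0.79), CG14780 (0.77), CG34331 (0.72) and wus (0.69). Without the level filter, 202 genes were 2-fold lower and 169 higher, and at a mean RPKM of at least 5 it was 44 and 10.

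The X-linked housekeeping genes had 19 of 20 members below the autosomal median after MSL2 RNAi (list median −0.43, below all 10000 random lists). Both values follow from the X-wide fall, since 91.5% of all X-linked genes lay below that median. Matched to other X-linked genes, in a comparison chosen after the data were seen, the list was at percentile 1.39. Among the lowest members were nej (−0.82), the septate junction gene dlg1 (−0.71) and the clathrin heavy chain gene Chc (−0.62). After CLAMP RNAi the same list was at −0.08 (percentile 5.43), with 11 of 20 below. The autosomal housekeeping genes lay above the autosomal median after MSL2 RNAi for 13 of 15 members (median 0.16, percentile 96.2, or 92.1 against lists matched also on X-linkage), with the aldolase gene Ald1 at 0.48 and the tubulin gene alphaTub84B at 0.46. After CLAMP RNAi they were at 0.01 (percentile 37.4).

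Glycolysis and lactate genes were higher as a list after MSL2 RNAi, with 9 of 13 members above the autosomal median (median 0.22, percentile 99.5). Ldh, the lactate dehydrogenase gene, had 17159 reads in control, 11873 after CLAMP RNAi and 33136 after MSL2 RNAi. Phosphofructokinase Pfk stood at 0.68 and Pglym78 at 0.50. After CLAMP RNAi the list median was 0.01 (percentile 47.2). Lipid and sterol synthesis genes were below the autosomal median for 9 of 10 members after MSL2 RNAi (median −0.17, percentile 3.55), with mdy, a diacylglycerol acyltransferase gene, at −0.69 and the fatty acid synthase gene FASN1 at −0.37. This list has no X-linked member, and against random lists without X-linked genes its percentile was 0.520. An unusual control library stays open for the lipid list here too, as given above.

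The remaining list medians lay within the central 95% of level-matched random lists after MSL2 RNAi. Hemocyte markers had a median of −0.04 (percentile 15.1), although Hml (0.95), Ppn (0.80) and Pxn (0.79) were higher here too and trol, an X-linked perlecan gene, was at −0.62. Cytosolic ribosomal protein genes were at 0.08 (percentile 77.4), mitochondrial ribosomal protein genes at 0.04 (97.3, or 97.6 when matched also on X-linkage, which is outside that range), histone gene expression factors at −0.17 (6.88), immune genes at −0.01 (51.9) and germline markers at −0.05 (39.4). Proteasome genes were at 0.10 (92.6), with the X-linked Prosalpha4 at −0.40 and Rpt3 at −0.31. Heat shock protein genes were at 0.13 (96.8, or 93.4 when matched also on X-linkage), with Hsp27 at 0.61 and Hsp70Ba, one of several near-identical copies, at −0.49. Cell cycle and replication genes were at 0.07 (94.9), with the X-linked cyclin gene CycD at −0.57 and stg at 0.43. Apoptosis genes were at 0.08 (89.9), while the cell death inducers rpr and hid stood at −0.95 and −0.92.

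Chromatin lists moved little in either comparison. After MSL2 RNAi the NSL complex and its partners had a median of 0.02 (percentile 57.6; E(bx) −0.42), insulator proteins −0.05 (30.3; Elba2 −0.38), heterochromatin factors 0.02 (70.0; the X-linked Hmr −0.58) and Polycomb and trithorax genes −0.07 (31.3; kis −0.61). After CLAMP RNAi the medians in that order were −0.08 (percentile 18.0), −0.11 (14.8, with Ibf1 at −0.56), −0.14 (8.90, with the heterochromatin protein 1a gene, CG8409, at −0.39) and −0.09 (35.9, with kis at −0.53). Sex determination genes were at −0.05 after CLAMP RNAi (percentile 60.5, her −0.24) and −0.04 after MSL2 RNAi (52.2, the X-linked snf −0.50). RNA interference genes were at −0.18 (4.98, Dcr-2 −0.28) and −0.01 (58.8, AGO1 −0.20). Ecdysone response genes were at 0.04 (91.7, br −0.71) and −0.14 (14.7, Eip74EF −0.41). JNK and JAK-STAT genes were at −0.01 (68.2, Mmp1 0.53) and −0.12 (7.83, Mmp1 −0.40).

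After CLAMP RNAi, mitochondrial ribosomal protein genes were at −0.02 (percentile 93.7, mRpL33 −0.74), proteasome genes at 0.01 (51.9, Rpt6R −0.38), heat shock genes at −0.09 (14.7, Hsp70Ba −0.88), cell cycle genes at −0.08 (10.8, stg 0.56) and apoptosis genes at 0.05 (92.9, wgn 0.57). Few markers of other cell types were expressed. Only 5 of 14 neuronal markers, 4 of 17 muscle markers and 3 of 10 Kc-type and epithelial genes reached a mean RPKM of 1. Neuronal markers had medians of −0.17 and 0.07 after CLAMP and MSL2 RNAi (percentiles 30.4 and 81.6), muscle markers −0.25 and −0.18 (15.7 and 21.0), and Kc-type and epithelial genes −0.17 and 0.28 (45.1 and 78.9). At a mean RPKM of at least 5 the neuronal median after MSL2 RNAi was −0.26, on the other side of 0. Members of largest change were Nrg, sls (−0.52 and −1.43), Tm1 (−0.71 and −0.24), sdt (−0.86 and −0.32) and crb (−0.16 and 0.81).

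The knockdown libraries were also compared with each other, which leaves the control out. X-linked genes had a median log2 ratio of −0.27 for MSL2 RNAi over CLAMP RNAi and autosomal genes 0.08. The difference was −0.35 (95% interval over genes −0.36 to −0.34), a ratio of 0.783, and lay below all 10000 random lists. Of the X-linked genes, 90.1% lay below the autosomal median.

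Some X-linked genes were lower in both knockdown libraries. Of the 42 X-linked genes 1.5-fold lower after CLAMP RNAi and the 192 after MSL2 RNAi, 21 were the same genes, Nrg and CR40469 among them. Independent lists of these sizes would share 6.26, and simulated counting noise against the shared control gave a mean of 0.730 and at most 5 in 100 simulations. The simulation gave each gene the same rate in every library and so left out the X-wide fall after MSL2 RNAi. Its X-linked numbers are therefore no baseline for the 21 shared genes. On the autosomes 68 genes were shared among those lower (7.55 for independent lists, simulated mean 3.53) and 24 among those higher (2.73 and 5.37). The single control library cannot be split, so part of the excess may come from that library. With a 2-fold rule 3 X-linked genes were shared, with a pseudocount of 1 there were 14, at a mean RPKM of at least 5 there were 12, and without the level filter 56.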

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

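No paired analysis was possible because each mRNA group has 1 library and the numbered immunoprecipitation replicates were not analysed here. Every alternative kept X-linked genes below autosomal ones in both comparisons with the MSL2 RNAi library, and over 9 alternatives the difference stayed between −0.36 and −0.29 against control and between −0.36 and −0.28 against CLAMP RNAi. For CLAMP RNAi over control it stayed between −0.01 and 0.00. With a pseudocount of 1 the differences were −0.33 against control and −0.33 against CLAMP RNAi, and without the level filter −0.29 and −0.28. Counts of genes past a rule of size moved most. For CLAMP RNAi, 2-fold lower genes numbered 43 with a pseudocount of 1, 241 without the filter, 32 at a mean RPKM of at least 5 and 52 at 1 kb or more, and 2-fold higher genes 131 without the filter and 20 at a mean RPKM of at least 5. For MSL2 RNAi, in that order, 44, 202, 44 and 40 genes were 2-fold lower and 22, 169, 10 and 28 were 2-fold higher. The percent of X-linked genes 1.5-fold lower after CLAMP RNAi was 5.19 without the filter, 1.90 at a mean RPKM of at least 5, 2.32 at 1 kb or more and 1.09 by the 2-fold rule. After MSL2 RNAi it was 10.4 with a pseudocount of 1, 17.1 with the autosomal median at 0, 12.9 with upper-quartile scaling and 1.71 by the 2-fold rule. X-linked genes lower in both libraries numbered 56 without the filter, 12 at a mean RPKM of at least 5, 12 at 1 kb or more, 14 with a pseudocount of 1 and 3 by the 2-fold rule. Without the filter the X to autosome ratio of median RPKM was 1.19 in control, 1.26 after CLAMP RNAi and 0.977 after MSL2 RNAi. A level or length filter changes how many genes are tested, and a larger pseudocount shrinks ratios of low genes by construction; for the scalings the cause was not tested. The other 78 values for the main comparisons stayed within their interval or, for counts, within 1.5-fold inclusive, the isoform alternatives among them, which were added after seeing the data. Of the values for single genes and lists, 37 left their interval and 249 did not. Single genes were run for the RNAi targets, the MSL complex and roX genes and the named lowest and highest genes, but not for list members. None of these genes past 2-fold and no list median outside the central 95% of random lists changed sign. Among the others, 3 genes (Clamp after MSL2 RNAi, msl-2 and msl-3 after CLAMP RNAi) and 7 list medians did. With the autosomal median at 0, the NSL complex and heterochromatin lists after MSL2 RNAi were at −0.01 and 0.00, and the mitochondrial ribosomal and JNK and JAK-STAT lists after CLAMP RNAi at 0.04 and 0.05. At a mean RPKM of at least 5, after MSL2 RNAi, immune genes were at 0.02 (also 0.02 after CLAMP RNAi, from 0.05), RNA interference genes at 0.01 and neuronal markers at −0.26. Depth limits genes with few reads, such as PGRP-SD with 27 reads in control, while the missing replicates limit every result.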

Other observations

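Ratios to control were patterned along the autosomes as well. A stretch of 57 neighbouring genes on distal 3L, from mu2 to Iml1, had a median log2 ratio of 0.20 after CLAMP RNAi, with 14.0% of its genes below the autosomal median, and 0.05 after MSL2 RNAi. In MSL2 RNAi over CLAMP RNAi the same stretch was at −0.15, with 82.5% of its genes below, so it is the CLAMP RNAi library that differs from both others there. Weaker low values between the knockdown libraries were seen around it and elsewhere. In MSL2 RNAi over CLAMP RNAi, where the autosomal median was 0.08, the 3L stretches from Eip63E to Sk2, from scramb2 to Cnb and from cue to CG3402 were at −0.08, −0.07 and −0.02, and 4 adjoining stretches of distal 2L, from CG3294 to Saf6, were between −0.06 and −0.02. After CLAMP RNAi these 2L stretches were between 0.03 and 0.07, and after MSL2 RNAi between −0.09 and 0.08. The stretch from Cwc25 to Wdr62 was at −0.09 after MSL2 RNAi, so the difference there is not of the CLAMP RNAi library alone. Whether the CLAMP RNAi culture had another copy number of these regions was not tested, so the values cannot be assigned to the loss of CLAMP. The genes nearest the centromere on 2R, from CG41257 to CG14471, were at −0.28 after CLAMP RNAi and −0.28 after MSL2 RNAi. With the control left out, in MSL2 RNAi over CLAMP RNAi, they were at 0.03 against that median of 0.08, so an unusual control library stays open for this stretch. The first stretch of 3L was at −0.18 and −0.13, that of 2L at −0.16 and −0.05, and that of 3R at −0.04 and 0.05. Beyond these first stretches, the other 100 stretches of the major arms ranged from −0.17 to 0.20 after CLAMP RNAi and from −0.09 to 0.14 after MSL2 RNAi. Across genes, which are not independent replicates, ranks taken within each autosomal arm were pooled and correlated between adjacent genes. The value was 0.174 after CLAMP RNAi and 0.160 after MSL2 RNAi, above the highest of 1000 shuffles within arms (0.0802 and 0.0799). Unequal arm sizes raise these values and the shuffles alike, so only the excess over the shuffles bears on neighbours.

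On chromosome 4, 49 of 57 genes lay below the autosomal median after CLAMP RNAi and 54 after MSL2 RNAi. Broadly expressed genes of that chromosome took part, picked here after their values were seen. RpS3A, a ribosomal protein gene, had 328918 reads in control, 253318 after CLAMP RNAi and 278208 after MSL2 RNAi, and eIF4G1, a translation initiation factor gene, had 56050, 44436 and 44165. Other members did not follow in both, since yellow-h stood at −0.03 and −0.95 and CG32021 at −0.01 and 0.66. The autosomal genes with the longest genomic spans, as a quintile, were at −0.11 after MSL2 RNAi and −0.08 after CLAMP RNAi.

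The tests that leave the control out, the lists without X-linked genes, and the test of length and level for the X, were chosen after their results were seen, whereas the values of the remaining tests were unknown when their predictions were written, for patterns noticed in these same libraries.

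Chromosome 4 genes were lower in both knockdown libraries, by −0.28 and −0.36 relative to the major arms. Transcript length and expression level are argued against, since the chromosome 4 median after CLAMP RNAi was at percentile 0 of lists matched on both, and long genomic spans of the genes gave percentile 0 too. Ordinary regional variation along chromosomes left 0% of 5834 overlapping autosomal stretches with a median as low, although the lowest, at −0.28, came near the chromosome 4 value of −0.34. The stretches in this and the next paragraph overlap and are not independent regions. A control library that stands apart stays open for most of the difference, because in MSL2 RNAi over CLAMP RNAi it was −0.069 (95% interval over genes −0.12 to −0.03, 44 of 57 genes below the autosomal median), and 1 high control cannot be told apart from an effect of both knockdowns; the remainder lay at percentile 0.910 of level-matched lists without X-linked genes, but 9.62% of autosomal stretches had a median as low. A change in the copy number of chromosome 4 between cultures and an effect of both proteins are further possible explanations that were not tested.

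X-linked genes were lower in the MSL2 RNAi library. A control library that stands apart is argued against by the difference of −0.35 with the control left out. Transcript length and expression level gave percentile 0 among matched lists, and ordinary regional variation along chromosomes left 0% of autosomal stretches as low as the median X stretch of −0.34. An effect of the loss of MSL2 and a difference of that single culture in X copy number were not tested and both stay open. The read ratios of roX1 and roX2, 0.336 and 0.205, lay far below the X-wide ratio of 0.781, so an X copy number that gave the X-wide ratio would not account for these 2 genes, but they do not show what lowered the others.

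Transcripts under 400 bases, 212 of the 7485 tested, were frequent among genes past 2-fold in both directions, making up 23 of 87 lower and 7 of 44 higher genes after CLAMP RNAi and 18 of 73 lower and 5 of 44 higher genes after MSL2 RNAi. A wider scatter of short transcripts was not tested and stays open for these counts. Their median was −0.15 after CLAMP RNAi, where level-matched lists had a median of −0.09 (percentile 0.310). After MSL2 RNAi it was −0.16 against −0.01 (percentile 0). The predicted loss of short transcripts relative to control was thus seen in both medians. The class holds the short genes that prompted the test, and a lower median does not say what lowered it. In MSL2 RNAi over CLAMP RNAi these transcripts were at 0.01 and longer ones at 0.05, which leaves a difference in size selection between the control library and the others as a candidate explanation, and no biological explanation was tested. Among the named genes, CR40469, RpL39, mRpL33 and CR33789 are in this class. CR40469 (−1.52 and −1.74), RpL39 (−0.81 and −1.58) and CR33789 (−1.32 and −1.56) lay far below the class medians after CLAMP and MSL2 RNAi.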
